A study of Populus davidiana with 6 samples.

How the data were processed

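The series holds poly(A)-selected RNA-seq libraries of Populus davidiana leaf, made with a TruSeq RNA kit and sequenced as paired reads of 100 bp, per the labels' protocols. The labels give 6 samples of 1 cultivar, Seogwang15, which they describe as drought-sensitive. The plants were about 6 weeks old and grown in sterile culture. In the 3 air-dried samples the plants were pulled from the medium, rinsed, and then air-dried for about 10 min; the other 3 samples are controls. The labels do not say whether the control plants were also pulled and washed. A second, tolerant cultivar that the growth protocol mentions was not analysed here.

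Each library came as 1 table with the same 112919 transcripts, of which 45773 are marked as known (annotated) and 67146 as added by the assembly, grouped by the authors into 40537 genes. The values are FPKM, fragments scaled by transcript length and by the mapped fragments of the library, calculated by the authors for each transcript, per the file headers. FastQC, TopHat and Cufflinks are listed, without versions, in the submitters' processing notes. The genome build and annotation release are not given in the sources used here; coordinates below are those of the deposited tables. The gene identifiers (POPTR_ followed by a number) come from a Populus annotation, and identifiers that start with XLOC were given to loci put together by the assembly. The gene name column was empty (0 names) and no reference was used here, so the tables do not pair the identifiers with gene names or functions. The 28 gene lists (abscisic acid, dehydrins, heat shock proteins, transcription factor families and others, with markers of other tissues) that were fixed before the data were examined match on names or descriptions, so 0 of them could be tested. The planned list comparison and its alternatives are therefore absent, and markers of other tissues could not be checked.

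For gene values, the FPKM of all transcripts of a gene were summed. Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, air-dried against control, and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. The fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The same test was run on each transcript. Counts of calls in kinds of gene models, chromosomes and transcript kinds were compared with Fisher's exact test, two-sided. Genes are not independent replicates in these tests or in the permutation tests over genes below. Their p-values therefore do not measure the spread between samples. On simulated data made from the residuals of the 22818 tested genes of the air-dried against control comparison, with 200 changed genes, the test recovered 43 of 100 genes changed by 1 on the log2 scale and 83 of 100 changed by 2, with 0 false calls. The changes were planted only in genes above a set control level, so recovery in the lowest genes was not measured. The residuals were centred within each group. The 0 false calls therefore do not cover differences between the groups other than the planted ones. The 200 changed genes are also fewer than the 1829 called in the data.

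The identifiers named are chosen by a rule fixed before the data were examined for the case that names are missing: at most 2 that rose and 2 that fell, with the largest change among called genes whose 3 air-dried values all lie on one side of the 3 control values. The alternatives tried were other pseudocounts, filters, scalings and variance settings, a replicate block, and leaving out each library; those added after the data were seen are named as such where their values are given. The labels do not say whether the 3 samples of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical. No pair of libraries held identical values (0 pairs).

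The tables give no read counts and the total depth is unknown. In low, long annotated genes with 1 transcript, the ratio of control 2 to control 3 lay within 0.03 log2 of -0.21 in 27.4% of 1118 genes, and that of air-dried 2 to air-dried 3 within 0.03 of 0.25 in 26.7% of 1384 genes, so 1 fragment was worth 0.865 times as much in control 2 as in control 3 and 1.19 times as much in air-dried 2 as in air-dried 3. Ratios that involve a replicate 1 library had no such peak (at most 9.88% of genes within 0.03 of any one value), and between groups the replicates 2 and 3 reached 9.53% to 12.8%. Why the peak was weaker between groups was not tested. A technical difference between the groups could not be told apart from the treatment. An exact 0 can be a failed estimate: 68 genes with over 10 FPKM in each of the other 5 libraries were listed at 0 in control 1, against 23 in air-dried 1 and 1 to 4 in the remaining libraries. Such genes are described as listed at 0.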

Results

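Leaf transcriptomes of Populus davidiana, an aspen, were compared between 3 samples from air-dried plants and 3 control samples, to find the genes whose transcript levels differed after about 10 min of drying in open air. Between 21766 and 22512 genes reached 1 FPKM in a library, and 22818 of the 40537 genes were tested. The first library of each group stood apart from the others. Control 1 held 191 transcripts above 10000 FPKM and air-dried 1 held 93, against 12 to 18 in each of the other 4 libraries. On log2(FPKM + 1) over the tested genes, control 1 correlated with the other libraries at r = 0.55 to 0.67 and air-dried 1 with the replicates 2 and 3 of both groups at r = 0.78 to 0.83, while the replicates 2 and 3 correlated with each other at r = 0.90 to 0.94. These are correlations across genes, which are not independent replicates. The lowest value, 0.55, was that of control 1 with air-dried 1, so the replicate 1 libraries were the least alike pair. In a principal component analysis, control 1 lay at -233 on component 1 (59.7% of the variance), against 28.2 to 79.0 for the others. Air-dried 1 lay at 137 on component 2 (23.5%), against -53.7 to 22.1. On component 3 (7.57%), controls 2 and 3 lay at -37.2 and -47.5 and air-dried 2 and 3 at 39.3 and 55.6. The replicate 1 libraries lay between these. Because each group holds 1 library that stood apart, each main count is also given without both replicate 1 libraries. This alternative was chosen after the data were seen. In loci assembled from the reads that spanned up to 150 bp, the median log2 ratio of control 1 to controls 2 and 3 was 4.78 and that of air-dried 1 to air-dried 2 and 3 was 4.53. In annotated genes over 1000 bp with 1 transcript these ratios were 0.05 and -0.02.

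**Figure D1:**
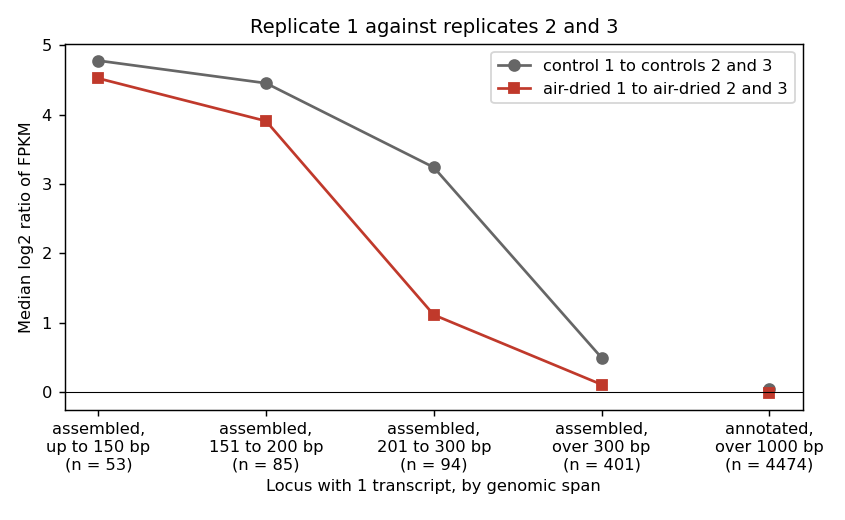
Median log2 ratio of FPKM of each replicate 1 library to the mean of replicates 2 and 3 of its group, for loci with 1 transcript above 0 in all libraries, by genomic span; n is the number of loci. The ratio falls from 4.78 and 4.53 in the shortest assembled loci to 0.05 and -0.02 in annotated genes over 1000 bp.

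Air-drying was followed by a change in 1829 genes, 8.02% of those tested, of which 1231 rose and 598 fell. The genes that rose moved further: 484 rose at least 2-fold and 98 fell at least 2-fold. At 3 or more on the log2 scale, 55 genes had risen and 5 had fallen. The median log2 change was 0.81 among the genes that rose and -0.59 among those that fell, and it was 0.03 over all tested genes. By the mean over all 6 libraries, the genes that fell had a median level of 27.1 FPKM, those that rose 16.5 FPKM and those that did not pass 12.1 FPKM (rose against fell, permutation test over genes, two-sided, p = 1e-05, the smallest that 100000 permutations can give). That test treats genes as independent, which they are not, so its p does not measure the spread between samples. Among tested genes with a mean of 100 FPKM or more, 112 rose and 107 fell, whereas among those with a mean of 1 to 5 FPKM 225 rose and 55 fell. All 1829 changed genes had their 3 air-dried values on one side of the 3 control values. With 3 samples per group a gene can hardly be called otherwise, so this is no separate support for the calls. The same arrangement was seen in 33.8% of all tested genes, and chance gives it for 10% of genes. Genes are not independent, so these shares were not compared by a test.

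**Figure D2:**
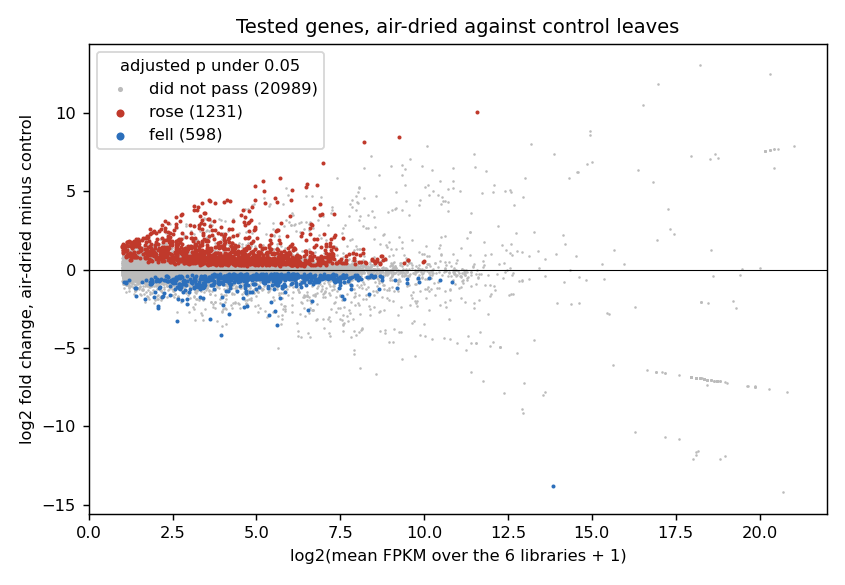
Log2 fold change of each tested gene, air-dried minus control, against log2 of its mean FPKM over the 6 libraries plus 1. Each point is a gene; the 1231 genes that rose reach further from 0 than most of the 598 that fell, and most points at the far right, the highest mean levels, are genes that did not pass.

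The counts depended on the libraries used and on the model fitted. Without both replicate 1 libraries, limma called 2767 genes, of which 1824 rose and 943 fell, and 1512 of the 2767 were also called, in the same direction, with all 6 libraries. At least 2-fold changes then numbered 704, with 549 genes up and 155 down, so the number that fell at least 2-fold was more than 1.5 times the 98 found with all libraries. They numbered 287 up and 47 down without air-dried 2, 272 up and 48 down without air-dried 3, and 335 up and 55 down without control 3. Leaving out a single library gave 724 genes without control 2, 639 without control 3, 1217 without air-dried 1, 476 without air-dried 2, 474 without air-dried 3 and 1995 without control 1. A replicate block with all 6 libraries gave 661 genes, of which 372 changed at least 2-fold. The replicate 1 libraries hold 1 sample per group and allow no test of their own. Of the 2767 genes called in replicates 2 and 3, 2498 (90.3%) differed in the same direction between air-dried 1 and control 1, against 61.8% of the 20051 genes not called. The median log2 difference in that separate pair was 0.61 for the genes that rose in replicates 2 and 3 and -0.57 for those that fell, compared with 0.68 and -0.55 in replicates 2 and 3 themselves.

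Some genes were listed near 0 in the controls and well above it in the air-dried libraries, although an exact 0 can be a failed estimate. Under 1 FPKM in every control and at least 5 FPKM in every air-dried library were 27 of the genes that rose, with a median air-dried level of 16.3 FPKM, while 4 of the genes that fell did the reverse. Of the 27, 23 were models tied to annotated genes, 22 spanned 500 bp or more of the genome, and 6 were listed at exactly 0 in all 3 controls. A model tied to an annotated gene need not hold an annotated transcript. The only transcript of POPTR_0003s21960.r1, which is among the 23, was added by the assembly. Without both replicate 1 libraries the numbers were 48 that rose and 10 that fell in this way, again by limma at an adjusted p under 0.05. The limits then had to be met in fewer libraries, so these counts cannot be set directly against the 27 and 4.

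The largest changes by the naming rule belonged to models listed at or near 0 in one group, and most of them were short. POPTR_0003s21960.r1, on the minus strand of chromosome 3 from 19929529 to 19935440, was listed at 0 in all 3 controls and at 17892, 217 and 302 FPKM in air-dried 1, 2 and 3 (limma adjusted p = 0.029). The unannotated locus XLOC_032617, 121 bp on chromosome 6 from 12652303 to 12652423 with no strand given, was listed at 0 in the controls and at 3418, 87.8 and 132 FPKM in the air-dried libraries (limma adjusted p = 0.027). XLOC_038063, an unannotated locus of 102 bp on chromosome 9 from 10827276 to 10827377, had 74102, 4985 and 8218 FPKM in controls 1, 2 and 3 and was listed at 0 in every air-dried library (limma adjusted p = 0.0025). XLOC_040198, an unannotated locus of 319 bp on the plus strand of an unplaced scaffold from 4422 to 4740, had 45.9, 13.9 and 23.7 FPKM in the controls and was listed at 0, 1.90 and 0 FPKM in the air-dried libraries (limma adjusted p = 0.017). The replicate 1 library held the highest of the 3 values of the higher group in each of these 4 models. The calls of POPTR_0003s21960.r1 and XLOC_032617 were lost without any one of control 1, control 2, control 3, air-dried 2 or air-dried 3, and that of XLOC_040198 without control 3, air-dried 1 or air-dried 3. In those fits the log2 changes were 10.05 to 11.18, 8.42 to 9.40 and -4.21 to -3.92, compared with 10.05, 8.42 and -4.18 with all libraries. XLOC_040198 also missed the threshold when both replicate 1 libraries were left out (log2 change -3.49, limma adjusted p = 0.059), while POPTR_0003s21960.r1 (8.01) and XLOC_032617 (6.76) passed it. With robust variance estimates POPTR_0003s21960.r1 (limma adjusted p = 0.060) and XLOC_032617 (limma adjusted p = 0.054) missed the threshold at the same log2 change, and rescaling every library to the same total ended all 4 calls. A replicate block ended the calls of POPTR_0003s21960.r1, XLOC_032617 and XLOC_040198 (limma adjusted p = 0.075, 0.072 and 0.087).

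The changes with the smallest p in each direction, which were chosen after their values were seen, belonged to annotated genes. A gene on the plus strand of chromosome 14 from 1643749 to 1644810, with 2 transcripts, rose from 4.14 ± 0.376 FPKM (SD, n = 3) in the controls to 219 ± 1.61 FPKM (SD, n = 3) after air-drying, 52.9 times the control mean (log2 change 5.42, SE 0.070, limma adjusted p = 3.4e-05). A gene on the minus strand of chromosome 9 from 7134992 to 7138967, with 3 transcripts, fell from 159 ± 4.74 FPKM (SD, n = 3) to 25.4 ± 0.530 FPKM (SD, n = 3), a control mean 6.23 times the air-dried mean (log2 change -2.59, SE 0.052, limma adjusted p = 6.8e-05). In both genes the replicate 1 values lay with those of replicates 2 and 3.

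**Figure D3:**
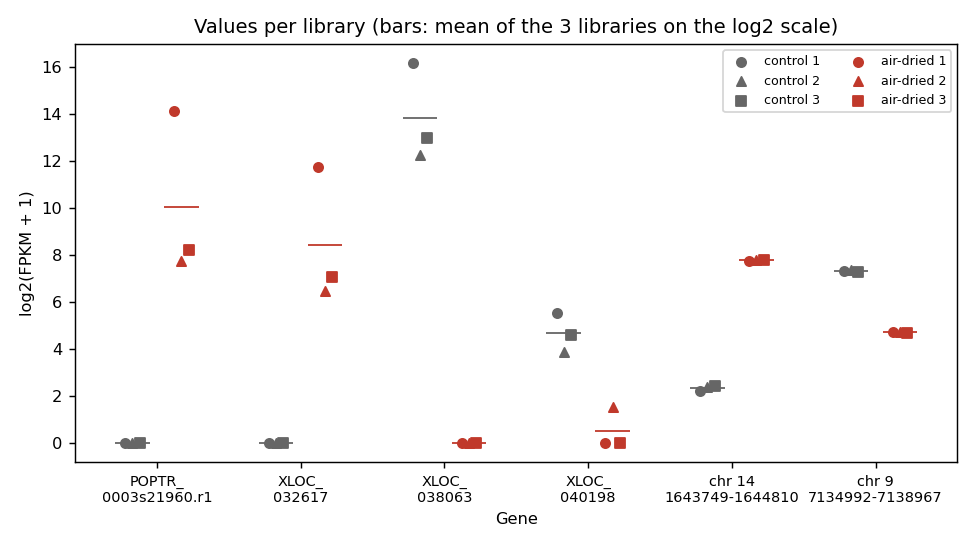
log2(FPKM + 1) of each library for the 4 models named by the rule and for the gene with the smallest p in each direction, given by chromosome and position. Marker shapes stand for replicates and horizontal bars for the mean of the 3 libraries on the log2 scale; replicate 1 is the highest point in the 4 rule-named models, while the 3 libraries of a group coincide in the genes on chromosomes 14 and 9.

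Among the tested genes, the share that rose was highest in annotated genes to which the assembly had added no transcript. In this class 501 of 5070 tested genes rose (9.88%) and 140 fell (2.76%). Among annotated genes with added transcripts, 603 of 14204 rose (4.25%) and 380 fell (2.68%). The filter on the mean kept 5070 of the 20896 genes without added transcripts and 14204 of the 15484 with them. The shares therefore hold for tested genes only and depend on which genes passed the filter. Loci that merge several annotated genes gave 113 rises (5.15%) and 46 falls among 2194 tested. Of 1350 unannotated loci, 14 rose (1.04%) and 32 fell (2.37%). The share that rose was higher than in all other tested genes for the class without added transcripts (odds ratio 2.56, Fisher's exact test, adjusted p = 7.1e-50 over 8 tests) and lower for genes with added transcripts (odds ratio 0.564, Fisher's exact test, adjusted p = 1.2e-21) and for unannotated loci (odds ratio 0.174, Fisher's exact test, adjusted p = 1.1e-17). With all libraries, none of the 4 classes was shown to differ from the rest in the share that fell (Fisher's exact test, adjusted p = 0.24 to 0.66). When both replicate 1 libraries were left out, the shares that rose were 13.5%, 6.46%, 8.25% and 3.19% in the order given, and the shares that fell were 4.64%, 3.85%, 3.37% and 6.44%. The fallen share of unannotated loci was then above the rest (odds ratio 1.66, Fisher's exact test, adjusted p = 7.8e-05 over 8 tests) and that of genes with added transcripts below it (odds ratio 0.831, Fisher's exact test, adjusted p = 0.011). The rising share of unannotated loci stayed below the rest (odds ratio 0.364, Fisher's exact test, adjusted p = 2.2e-13). These loci are short, with a median span of 273 bp, against 1254 to 9400 bp in the other classes. In assembled loci up to 300 bp, control 1 lay a median of 3.24 to 4.78 log2 above controls 2 and 3. Such spread makes a change harder to call with all libraries, and its effect on the shares was not tested. About 11.7% of the tested genes, 9.75% of those that rose and 69 of the 598 that fell overlapped another tested gene, and the labels name no strand-specific protocol, so reads of overlapping genes cannot be told apart.

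**Figure D4:**
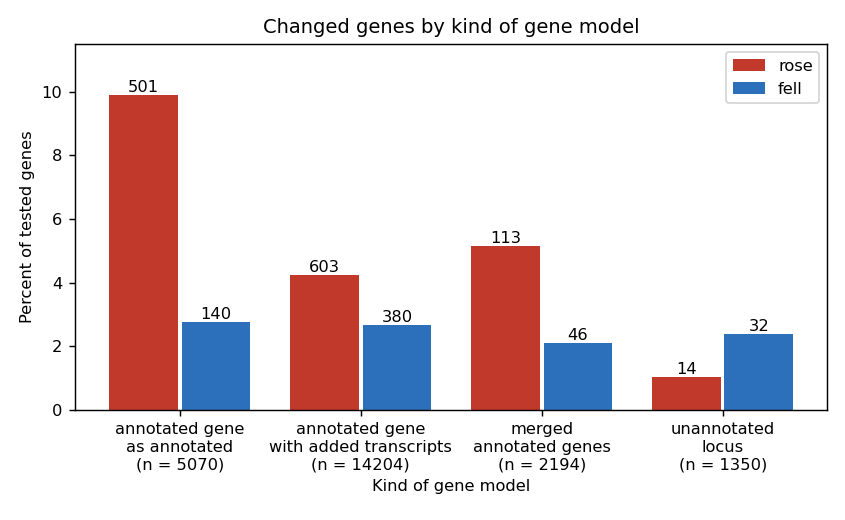
Percent of tested genes that rose or fell in each of 4 kinds of gene model, with the number of genes above each bar and the number tested in parentheses. The tallest bar is the 9.88% of annotated genes without added transcripts that rose.

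Changed genes lay on all 19 chromosomes. Of the genes placed there, 1202 rose and 580 fell, and a further 29 rose and 18 fell on unplaced scaffolds. Chromosome 3 had the highest share of rising genes, 91 of 1250 tested (7.28%), and chromosome 13 the lowest, 33 of 827 (3.99%). Neither share, nor any other chromosome's share of rises or falls, differed from the other chromosomes after adjustment over 38 tests (Fisher's exact test, adjusted p = 0.18 for chromosome 3 and 0.47 for chromosome 13).

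At the level of single transcripts, 1008 of 42451 tested transcripts changed, 673 upward and 335 downward. They belonged to 938 genes. The summed value of the gene changed as well in 628 of these and did not pass the test in 310. Annotated transcripts rose more often than assembled ones, 453 of 18794 (2.41%) against 220 of 23657 (0.930%) (Fisher's exact test, p = 9.5e-34), whereas their shares that fell, 0.867% and 0.727%, were not shown to differ (Fisher's exact test, p = 0.11). In 36 genes 1 or more transcripts rose while others fell, and in 24 of these the summed value did not pass. Without both replicate 1 libraries 1606 transcripts changed and 93 genes had transcripts in both directions. The transcript count depended strongly on the processing. It was 308 under median-of-ratios scaling and 646 without a filter on low values, and leaving out 1 library gave between 193 and 1172: 358 without control 2, 327 without control 3, 264 without air-dried 2 and 193 without air-dried 3. With a replicate block it was 71, and with array weights, chosen after the data were seen, 3718.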

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

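The array weights, the median filter, and the settings without replicate 1 libraries, without short transcripts or with annotated transcripts only were chosen after seeing the data. Of 22 alternatives for the 1829 changed genes, 11 stayed within 1.5 times, as did 17 of 21 for the 582 genes changed at least 2-fold and 11 of 21 for the 1008 transcripts. Leaving out 1 library gave 474 to 1995 genes, 320 to 600 genes at least 2-fold (334 without air-dried 2 and 320 without air-dried 3) and 193 to 1172 transcripts. Rescaling every library to the same total left 2 genes, 2 genes at least 2-fold and 2 transcripts, and moved the median log2 change of all tested genes to 0.17; 99.4% of the total of control 1 lay in transcripts above 10000 FPKM, so this total does not measure the library. Each transcript tested on its own gave 1008 calls. A replicate block gave 661 genes, 372 at least 2-fold (312 up and 60 down) and 71 transcripts, and did not call POPTR_0003s21960.r1, XLOC_032617 and XLOC_040198 (limma adjusted p = 0.075, 0.072 and 0.087) at the same log2 changes; over all tested genes the deviations of same-numbered libraries from their group means correlated at r = 0.02, 0.04 and 0.01 for replicates 1, 2 and 3, under the 0.1 set for a pairing, and control 3 correlated best with air-dried 2. The replicate 1 libraries nevertheless share their excess in very short loci, and the labels do not say what a number marks, so a batch behind number 1 stays possible and the block cannot be dismissed for it. Without both replicate 1 libraries 2767 genes and 1606 transcripts were called, and array weights, which gave control 1 a weight of 0.169 and air-dried 2 one of 3.26, gave 5334 genes and 3718 transcripts. Annotated transcripts only gave 1210 genes, from 17139 tested in place of 22818; of the 1829 genes, 917 were called in the same direction, 91 had the opposite sign and 240 were not tested. For transcripts, no filter on low values gave 646 and median-of-ratios scaling 308. The cause of these last changes was not tested. The 4 models named by the rule kept their direction in every alternative that tested them, and lost their call in 8 (POPTR_0003s21960.r1), 8 (XLOC_032617), 1 (XLOC_038063) and 6 (XLOC_040198). With an unknown depth, genes listed at 0 have no lower limit, and no gene list could be tested under any setting.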

Other observations

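The tests in this part were chosen after the main result was seen, except the count of other splits of the samples, which was planned. Median-of-ratios scaling and quantile normalization were planned as settings, but reading the share that rose under them was chosen afterwards. Neighbouring genes rose together more often than shuffled positions gave. The permutation p-values for neighbours are one-sided, from the shuffles with at least as many pairs. Those without the replicate 1 libraries were not adjusted. Among 20963 pairs of neighbouring tested genes that do not overlap, both rose in 86, against a mean of 62.6 (95% of shuffles 48 to 77) over 10000 shuffles of the calls within chromosomes (permutation p = 0.0015, adjusted p over 15 tests 0.0067), and both fell in 25, against 14.4 (permutation p = 0.0052, adjusted p 0.016). Pairs with 1 gene up and 1 down numbered 50, against 60.6. Among pairs at least 10 kb apart the excess did not pass the adjustment: both rose in 32, against 22.4 with an upper limit of 32 (adjusted permutation p = 0.056), and 1 rose and 1 fell in 29, against 21.4 (adjusted permutation p = 0.094). Without both replicate 1 libraries both rose in 159 pairs, against 135 (permutation p = 0.018); these were 93 same-strand pairs, against 63.6, and 63 opposite-strand pairs, against 62.2 (permutation p = 0.48), besides pairs with no strand given. In the same libraries both fell in 69 pairs, against 35.9 (permutation p = 1e-04, the smallest that 10000 shuffles can give), and in 53, against 31.3, among pairs at least 1 kb apart. Of runs of 3 or more adjacent tested genes with the same call, 8 rose and 2 fell. They include 3 genes on chromosome 3 from 14928871 to 14946666 with a mean log2 change of 1.96, 3 on chromosome 5 from 8399343 to 8419691 with 1.49, 3 on chromosome 3 from 13821924 to 13838517 with 1.40, and, among those that fell, 3 on chromosome 2 from 6581024 to 6614402 with -0.88. A run of 4 on chromosome 17 from 5627545 to 5844565, with a mean of 2.53, consists of overlapping models.

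Overlap between the models of a pair was left out of these counts from the start, since only neighbours that do not overlap were paired. Among pairs at least 1 kb apart, which are a part of the same pairs, both rose in 77, against a shuffled mean of 54.8 with an upper limit of 69. Reads that run on from a gene into the next one on its strand remain open. With all libraries, pairs on the same strand that both rose numbered 50, against 29.4 with an upper limit of 40 (adjusted permutation p = 0.0045). Those on opposite strands numbered 35, against 28.7 with an upper limit of 40. Same-strand pairs at least 10 kb apart that both rose numbered 15, against 10.4 with an upper limit of 17, and opposite-strand pairs at that distance 17, against 10.3 with the same upper limit (adjusted permutation p = 0.056). Neither opposite-strand count went beyond its limit. These counts cannot decide the question in any case. The labels name no strand-specific protocol, so run-on reads could also be counted in a neighbour on the other strand. The same-strand excess, seen with all libraries and without the replicate 1 libraries, goes with run-on reads, but copies of 1 gene in a row can also lie on the same strand. A candidate explanation that could not be tested without gene sequences is that such runs are copies of 1 gene, which may respond alike or share reads.

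More genes rose than fell, 67.3% of those changed. Scaling of the deposited FPKM is argued against as the whole cause: the share was 59.5% under median-of-ratios scaling (exact binomial 95% interval 57.3 to 61.8) and 63.8% under quantile normalization. The interval counts genes as independent trials, which they are not, and does not measure the spread between samples. Leaving out 1 library gave shares of 68.8% to 79.6%. The extreme values of the replicate 1 libraries are argued against by the share of 65.9% without both. A response to the treatment, which may include pulling and washing the plants as well as drying them, stays open and untested, since no sample separates these steps. A technical difference between the groups cannot be told apart from such a response.

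Control 1 and air-dried 1 carried far larger values than the other libraries, up to 11100000 and 12800000 FPKM. The excess followed the length of the locus. In loci assembled from the reads with 1 transcript and up to 150 bp, the median log2 ratio to replicates 2 and 3 of the same group was 4.78 in control 1 and 4.53 in air-dried 1; over 300 bp it was 0.50 and 0.11, and in annotated genes over 1000 bp 0.05 and -0.02. This is consistent with the length correction of very short transcripts, which depends on the fragment lengths of a library. Fewer fragments sequenced are argued against as the whole cause, since the low values of long genes (5th percentile of those above 0) were only 1.76 times as high in control 1 and 1.40 times in air-dried 1. Somewhat fewer fragments remain possible. Of the same long genes, 59.6% were listed at 0 in control 1, against 47.9% in control 2 and 48.9% in control 3. The share was 52.1% in air-dried 1, against 45.1% in air-dried 2 and 43.8% in air-dried 3.

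With 3 samples against 3 there are 10 splits, too few for a share under 0.05. In each of the 3 counts 1 of the 10 splits, the real one, was as large: the real split gave 1829 genes, 582 genes at least 2-fold and 1008 transcripts, and the highest of the others gave 6, 6 and 9.

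Among annotated genes with 1 transcript, the median span of the genes that rose was 1516 bp and that of genes that did not pass 1646.5 bp, a difference that missed the threshold (permutation test, two-sided, p = 0.053).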
